A study of Rattus norvegicus with 20 samples.

How the data were processed

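RNA of olfactory and respiratory nasal epithelium from untreated adult Sprague-Dawley rats was measured on 20 rat genome expression arrays, 1 per sample. Per the labels, total RNA was extracted with Trizol and a Qiagen kit from tissue kept in a preservative, and biotin-labelled copies were put on the arrays. The deposited values are in the unit intensity, a linear signal per probe set. The submitters' processing notes name GCOS 1.0, the array maker's operating software, and the algorithm within it, its scaling target and any later step are not given in the sources used here. The values show a scaling by the authors to a common level, since the mean after trimming 2% at each end lay near 500 on every array. Signals ran from 0.0637 to 76035, and the array medians spanned 0.48 on the log2 scale, under the limit of 0.5 set for a new scaling, so the deposited scaling was kept.

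Samples were grouped by the sex and tissue in their labels: 6 male olfactory, 6 male respiratory, 2 female olfactory and 6 female respiratory arrays. Samples whose labels carry the same sex and number were taken as 1 animal, which gives 13 animals and 7 with both tissues. This reading was checked on the data: over all probe sets, deviations from the group mean correlated by -0.184 to 0.246 between the 2 arrays of an animal, against medians of -0.097 to 0.125 with arrays of other animals, and were higher than these in 4 of 7 animals. The consensus correlation within animals was 0.039, so the pairing rests on the labels. The main model, fixed beforehand, holds no animal term, and the paired alternatives stand beside it, where 8034 probe sets passed in males with the animal as a random replicate block.

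Of 31099 probe sets 57 controls were left out and 31042 were tested. The annotation gave 1 gene symbol for 20826, several for 436 and none used here for 9780. Symbols were brought up to date by Entrez identifier for 20758, found by accession for 2 and kept as annotated for 66, and 1 changed. These name 14217 genes, 4525 of them with several probe sets, and a gene stands for its probe set with the highest mean log2 signal over all arrays. No genome positions were used here. The Gapdh and Actb probe sets match several genes, so the array maker's control probe sets served as reference: the 3' GAPDH probe set averaged log2 14.17 to 14.35 and the 3' beta-actin probe set 14.36 to 14.65 by group.

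Signals were taken to log2 after adding 16. limma 3.58.1 in R 4.3.3 fitted a mean for each of the 4 groups over all 20 arrays, with empirical Bayes variances that follow intensity. Contrasts were olfactory minus respiratory in each sex, female minus male in each tissue, and the difference of both tissue contrasts. Every p of these contrasts is limma's, two-sided, and adjusted by Benjamini-Hochberg over 31042 probe sets, with calls under 0.05, and SE is the standard error of limma's fit. Changes are log2 differences of group means unless named as fold. Background was set per array at the 95th percentile of 27 bacterial control probe sets that carry no target. Where all arrays of a group lie at or under it, the change is given as a bound of at least so many fold, with the fit's adjusted p.

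For 35 gene lists fixed beforehand, measured members called higher and lower were counted, camera tested each list against all other genes with its preset correlation of 0.01 and again with an estimated one, and fry tested each list alone, each adjusted over the 35 lists. Camera's preset correlation takes members as nearly independent. Counts adjusted over the list alone use Benjamini-Hochberg over its members. The lists cover olfactory signal transduction, olfactory receptors, vomeronasal genes, immature neurons, synapse, sustentacular cells, gland proteins, cytochromes P450, other phase 1 enzymes, glutathione transferases, UDP-glucuronosyl and sulfo transferases, other conjugating enzymes, transporters, oxidant defence, nuclear receptors, motile cilia, goblet, basal and squamous cells, leukocytes, MHC class II, interferon response, glia, endothelium, connective tissue, muscle, erythrocytes, cell cycle, immediate early genes, circadian clock, Y-linked and X genes, sex-dimorphic liver genes, hormone response and airway proteases. Lists of mast cells, ionocytes and tuft cells were added after the values were seen. From the fixed lists 3 matches that only share an old alias were removed.

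The groups, contrasts, tests, lists, rule for named genes and most alternatives were fixed before the data were examined. The rule names up to 10 genes per direction with the largest change among called genes whose groups do not overlap (in male tissue and in each sex contrast), the 3 members of each list with the largest change, all Y-linked genes and Xist. The genes outside it were chosen after their values were seen: these are the further list members named in small counts or as examples, Omp, Cpa3, Fcer1a, every probe set called between the sexes, and the members of the added lists.

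Alternatives were the animal as a random block (duplicateCorrelation) and as a fixed block in the 5 males with both tissues, pseudocounts of 1 and 64, quantile normalization, a shift to a common 75th percentile, filters at the 25th percentile and median of the mean signal, no variance trend, only the groups compared, age as a factor, comparisons within 11, 13 or 14 weeks, the RNA integrity number as a covariate without the 3 arrays that have none in their labels (male olfactory 4, male respiratory 1 and 7), the mean of all probe sets of a gene, all probe sets in camera, and leaving out each array in turn. Where this leaves 1 female olfactory array, or 1 male respiratory array within 13 weeks, it is assumed to vary like the arrays of the other groups. Leaving out the 2 arrays that stand apart, leaving out the 3 respiratory arrays highest in Omp (female respiratory 3 and 7, male respiratory 1), array quality weights and only the arrays with an RNA integrity number, without the covariate, were chosen after seeing the data.

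The fit was tested on simulated data of the same group sizes with 200 changed probe sets. At changes of log2 0.5, 1 and 2 it recovered 3.0, 22.4 and 84.8% in the male tissue contrast, 0, 6.0 and 54.5% in the female one, 1.5, 22.4 and 90.9% between sexes in respiratory and 0, 0 and 62.1% in olfactory epithelium, and 0, 1.5 and 43.9% of interactions, with at most 5 unchanged probe sets called per comparison. In 100 simulated lists of 20 genes camera with either correlation and fry found all 20 changed lists, and fry called 3 of 80 unchanged ones. Simulated genes do not move together as real ones do, so these numbers say little on correlated lists. The Benjamini-Hochberg adjustment is stricter where fewer probe sets change. The shares recovered therefore hold for 200 changed probe sets, and are too high for contrasts with few changes and too low for those with many. Array measures, correlations, exact permutation tests and figures came from Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Single values in groups of 4 to 10 arrays were screened with Dixon's test at 95%.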

Results

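Gene expression was measured on 1 array per sample in olfactory and respiratory epithelium from the noses of untreated adult Sprague-Dawley rats, an outbred laboratory stock. By the numbers in their labels the 20 arrays came from 13 rats, 7 male and 6 female, of which 7 (5 male and 2 female) gave both tissues, while the series text speaks of 9 rats of each sex. There were 6 male olfactory, 6 male respiratory, 6 female respiratory and 2 female olfactory arrays, from rats aged 11, 13 or 14 weeks. Each array gave 1 signal for each of 31042 probe sets, and the number of arrays limits the precision of what follows. The median signal per group was 161 ± 18 (SD, n = 6) in male olfactory, 173 ± 12 (n = 6) in male respiratory, 142 ± 13 (n = 2) in female olfactory and 177 ± 17 (n = 6) in female respiratory arrays. RNA integrity numbers, a score of how intact the RNA was, moved with the tissue: they averaged 8.54 ± 0.26 (SD, n = 5) in male olfactory against 9.20 ± 0.08 (n = 4) in male respiratory samples. In females they averaged 8.30 (n = 2) against 8.98 ± 0.26 (n = 6). In neither sex did the numbers overlap between the tissues, so RNA quality and tissue can hardly be told apart here. The 3' to 5' ratios of control genes, taken below as a sign of degraded RNA where high, did not all go the same way. In males their log2 averaged 0.17 in olfactory against 0.33 in respiratory arrays for GAPDH, 0.71 against 0.97 for hexokinase and 1.18 against 0.93 for beta-actin. The directions were the same in females.

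The first principal component of all probe sets carried 38.5% of the variance and set the tissues apart, with olfactory arrays from 66.4 to 110.9 and respiratory arrays from -81.4 to -29.0. The second carried 15.8%. Female respiratory array 8 and male respiratory array 7 lay at -113.35 and -97.55 on it, outside the range of the other 10 respiratory arrays.

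**Figure D1:**
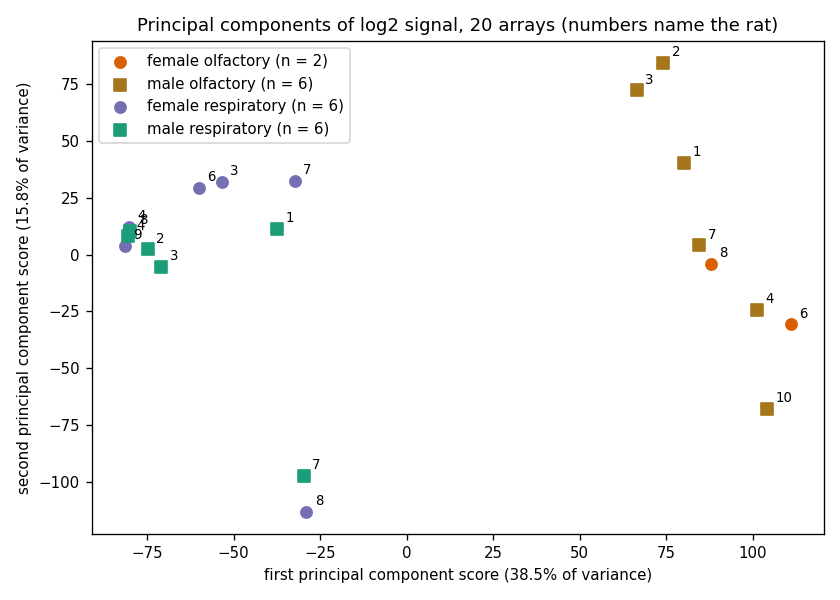
Each point is 1 of 20 arrays on the first and second principal components of log2 signal over 31042 probe sets (38.5% and 15.8% of the variance), coloured by sex and tissue and numbered by rat. Olfactory arrays lie at 66.4 or above and respiratory arrays at -29.0 or below, with female respiratory 8 and male respiratory 7 apart at the bottom.

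The main comparison asked how olfactory epithelium differs from respiratory epithelium, as a baseline for how the nose meets inhaled foreign chemicals. Among genes that parted the 6 male olfactory from the 6 male respiratory arrays completely, the largest rises in log2 signal were in Wdr17 (4.89, SE 0.43, adjusted p 2.2e-08), the opsin-like gene Rgr (4.75, SE 0.49), Gng13 (4.61, SE 0.51), a G protein subunit of sensory cells, Chga (4.34, SE 0.40), a protein of secretory granules, and Nrn1l (4.33, SE 0.37). Faim2, the olfactory chloride channel gene Ano2, Tmem213, Fgf12 and Gpr162 followed, at 4.32, 4.30, 4.27, 4.26 and 4.18. The largest falls were in Lpal2 (-7.48, SE 0.72, adjusted p 6.8e-08), Mup5 (-7.35, SE 0.59), a carrier of small scent molecules, the potassium channel subunit gene Kcne1 (-6.77, SE 0.45, adjusted p 6.0e-10), Dnase1 (-6.65, SE 0.75) and Glal (-6.46, SE 0.98). Csn3, Pip, Inhca and the airway mucin gene Muc5ac were also lower, at -6.45, -6.36, -5.84 and -5.74 (Muc5ac lay under background on male olfactory 2), and Serpinb2, at background on all 6 male olfactory arrays, was at least 24.0-fold lower (adjusted p 2.9e-07). In 6 male olfactory against 6 male respiratory arrays, 7824 of 31042 probe sets passed an adjusted p of 0.05 in limma, 3594 higher and 4230 lower in olfactory epithelium, and 5062 of them changed 2-fold or more (2293 higher, 2769 lower). They include 4517 of 14217 named genes, 1990 higher and 2527 lower. With the RNA integrity number as a covariate 2347 probe sets passed, 2247 of them among the 7824. On the same arrays without the covariate, a comparison chosen after seeing the data, 7203 passed. Of 165 named genes called in males 82 lost their call with the covariate and 14 without it on the same arrays. The SE was larger in all 82 (median ratio 1.78), and the change was at least 0.8 times the former in 39 and smaller in 43, a limit also chosen after seeing the data. Glal is among the 39, at -5.72 (SE 1.89 from 0.98, adjusted p 0.0749). A call is named as ended mainly by a larger SE where the change was at least 0.8 times the former, with its change under the covariate and the SE from before. With each animal as a fixed replicate block over the 5 males with both tissues 7493 passed, and within rats aged 11 weeks (3 males with both tissues) 7777 passed.

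Of 17 measured genes of olfactory signal transduction, which turns an odour into a nerve signal, 13 rose in males and 1 fell, with a median change of 3.18. Examples are Cnga2 (4.18, SE 0.40), the cyclic nucleotide channel of olfactory neurons, Adcy3 (3.78, SE 0.34), their adenylyl cyclase, Gnal (3.75, SE 0.49), their G protein, and Omp, the marker of mature olfactory neurons, at log2 14.54 ± 0.13 (SD, n = 6) against 10.70 ± 1.04 (n = 6). The member that fell was Gucy2d (-0.96, SE 0.31, adjusted p 0.0237), the receptor cyclase of a small set of olfactory neurons, and its call ended with the fixed animal block (adjusted p 0.146), within 11 weeks (0.451), with the RNA integrity covariate (0.255, at -1.20, SE 0.59) and without 1 array, most without male respiratory 3 (0.062). Of 18 odorant receptor genes 13 rose, among them Olr1493 (2.57, SE 0.30) and Or8g23 (2.66, SE 0.48). Or2b2 was at least 4.26-fold higher (adjusted p 1.8e-06). The receptors' median change was 1.75, or 1.09 with the 6 members at background on all arrays of a group set to their bound. Immature neurons and progenitors had 20 of 21 genes higher, with Stmn3 (3.87, SE 0.40), Stmn4 (3.16) and Stmn2 (3.02) of the stathmins that regulate microtubules, and synapse and excitability had 17 of 23 higher, with Uchl1 (3.77), the sodium channel gene Scn9a (3.40) and Stx1a (3.35). Of 14 vomeronasal genes 0 passed in limma and 1 had an unadjusted p under 0.05 (median -0.14), and Vom2r40, Vom2r53 and Vom2r-ps45 had adjusted p values of 0.528, 0.255 and 0.0751. By camera the first 4 lists passed with adjusted p values of 2.7e-08, 3.4e-07, 2.6e-14 and 2.1e-11, against 0.979 for the vomeronasal list. Receptors and synapse genes kept this with an estimated correlation (adjusted p 0.0492 for each), while transduction and immature neurons did not (adjusted p = 0.085 each with an estimated correlation). Fry, which tests a list without comparing it with other genes, called the first 4 lists higher (adjusted p 8.4e-07, 2.2e-07, 1.2e-06 and 1.1e-07) and not the vomeronasal one (0.645). Adjusted over the list alone, 16 transduction, 14 receptor, 20 immature neuron and 18 synapse genes passed, and no vomeronasal gene did. The RNA integrity covariate ended the calls of Or8g23 (1.11, SE 0.74 from 0.48) and Or2b2 (adjusted p 0.0738, SE 0.51 from 0.29), at less than 0.8 times the former change.

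**Figure D2:**
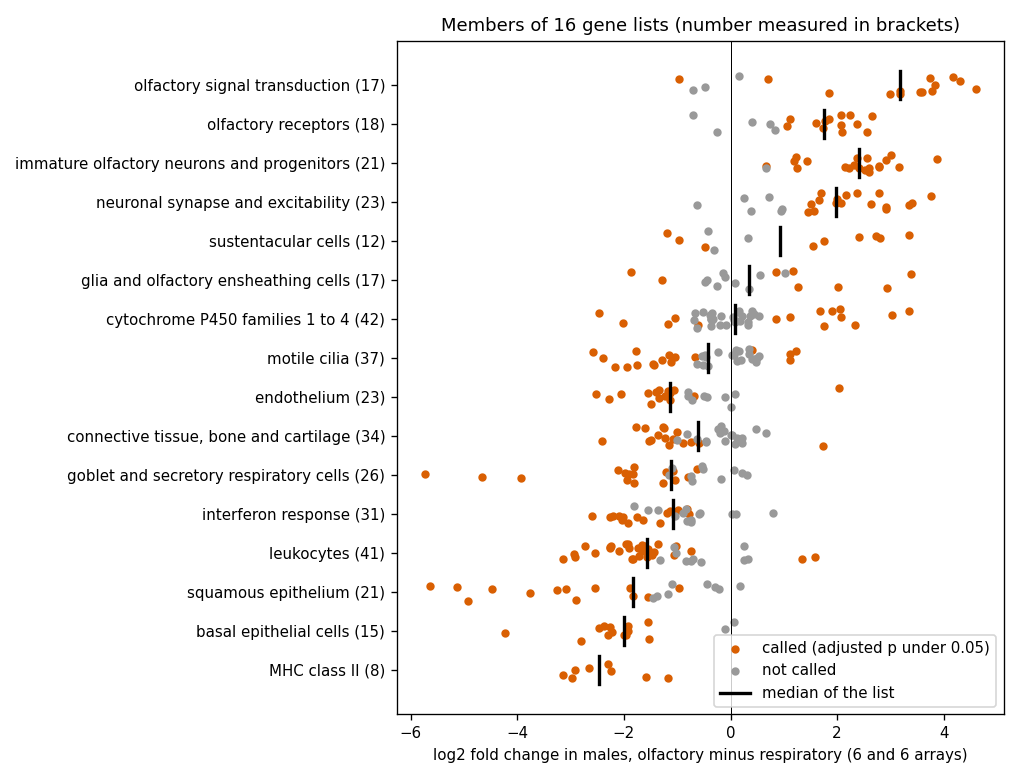
Each point is a measured gene of 16 fixed gene lists, placed by its log2 signal in male olfactory minus male respiratory epithelium (6 against 6 arrays), orange where limma's adjusted p is under 0.05, with a bar at the list's median. Medians run from 3.18 for olfactory signal transduction to -2.48 for MHC class II.

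Supporting and glandular cells split. Of 12 genes of sustentacular cells, the supporting cells of olfactory epithelium, 6 rose and 3 fell. Cyp1a2, a drug-metabolising cytochrome P450, rose by 3.35 (SE 0.42), the odorant-conjugating enzyme gene Ugt2a1 by 2.80 (SE 0.42) and Ermn by 2.73 (SE 0.43). Steap4, Hes1 and Sox2 fell (-1.19, -0.97 and -0.47), but Sox2 not without male olfactory 2 (adjusted p 0.0951). Of 18 odorant-binding and gland secretory proteins 1 rose, Bpifb4 (2.86, SE 0.52), and 7 fell, among them Dmbt1 (-4.51, SE 0.92), the odorant-binding protein gene Obp1f (-4.02, SE 0.62) and the airway defence gene Bpifb1 (-3.30, SE 0.35). Of 17 genes of glia and olfactory ensheathing cells, which wrap the olfactory axons, 6 rose and 2 fell: Fabp7 (3.39, SE 0.43), Gfap (2.93, SE 0.41) and S100b (2.02, SE 0.28) were higher and the myelin genes Mbp (-1.86, SE 0.30) and Prx (-1.29, SE 0.39) lower. Prx did not pass with the fixed animal block (adjusted p 0.0553) or within 11 weeks (0.117). The means of all Mbp and of all Sox2 probe sets (-0.34) were not called either (adjusted p 0.169 and 0.203). None of these lists passed by camera with 1 probe set per gene (adjusted p 0.121, 0.256 and 0.122), while the sustentacular list passed as higher over all probe sets (0.0265). Fry called sustentacular cells and glia higher (adjusted p 0.0189 and 0.0235) and gland proteins lower (0.00401), but no call held with an estimated correlation (adjusted p = 0.599, 0.575 and 0.599 with an estimated correlation). In these lists 9, 9 and 8 genes passed adjusted over the list alone. The RNA integrity covariate ended calls mainly by a larger SE for Sox2 (-0.46, SE 0.30 from 0.17) and Dmbt1 (-4.96, SE 1.67 from 0.92). It did so by a smaller change as well for Ermn (1.66, SE 0.67 from 0.43), Hes1 (-0.62, SE 0.49 from 0.25), Bpifb4 (2.04, SE 0.65 from 0.52), Obp1f (-3.20, SE 0.99 from 0.62), S100b (1.24, SE 0.47 from 0.28) and Mbp (-1.12, SE 0.53 from 0.30).

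The enzymes that act on inhaled chemicals went both ways. Of 42 genes of cytochrome P450 families 1 to 4, the main oxidases of drugs and odorants, 10 were higher and 5 lower in male olfactory epithelium. Among the higher were Cyp1a2, Cyp2b21 (3.02, SE 0.36), Cyp3a9 (2.34, SE 0.41), Cyp1a1 (1.90, SE 0.32), the olfactory form Cyp2g1 (1.75, SE 0.34) and Cyp2e1 (1.68, SE 0.28). The lower ones were Cyp4a8 (-2.46, SE 0.40), Cyp2t1 (-2.01), Cyp2s1 (-1.18), Cyp4f5 (-1.04) and Cyp4f6 (-0.61). The last 2 were lost with the fixed animal block (adjusted p 0.0942 and 0.104) and without 1 array (Cyp4f5 0.0756 without male olfactory 1, Cyp4f6 0.104 without male respiratory 7 or 8). Other phase 1 enzymes had 7 of 32 genes higher and 10 lower. The aldehyde and ketone reductase gene Akr1b8 (-5.17, SE 0.27, adjusted p 3.2e-11), the alcohol dehydrogenase gene Adh7 (-5.04, SE 0.53) and the aldehyde dehydrogenase genes Aldh3a1 (-3.67, SE 0.32) and Aldh1a1 (-1.60, SE 0.21) were lower, while Adh1c (2.44, SE 0.36), Adh5 (1.13, SE 0.19) and Por (1.05, SE 0.31), which feeds electrons to the cytochromes P450, were higher. Camera passed neither list (adjusted p 0.266 and 0.454), and fry called only other phase 1 enzymes, as lower (0.0187, against 0.0549 for the cytochromes P450, and adjusted p = 0.842 with an estimated correlation in camera), while 17 and 19 genes passed adjusted over the list alone. Cyp4f5 and Cyp4f6 were not called within 11 weeks (adjusted p 0.0953 and 0.407), nor Cyp4f6 with quantile normalization (0.0968). Under the RNA integrity covariate calls ended mainly by a larger SE for Por (1.06, SE 0.60 from 0.31), Cyp2t1 (-1.88, SE 0.77 from 0.44), Cyp2s1 (-1.33, SE 0.49 from 0.26) and Cyp4f6 (-0.82, SE 0.38 from 0.22). A smaller change as well ended those of Cyp3a9 (1.21, SE 0.62 from 0.41), Cyp1a1 (1.47, SE 0.57 from 0.32), Cyp2e1 (0.95, SE 0.45 from 0.28), Adh5 (0.85, SE 0.26 from 0.19), Cyp4a8 (-1.39, SE 0.53 from 0.40) and Cyp4f5 (-0.67, SE 0.64 from 0.34).

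**Figure D3:**
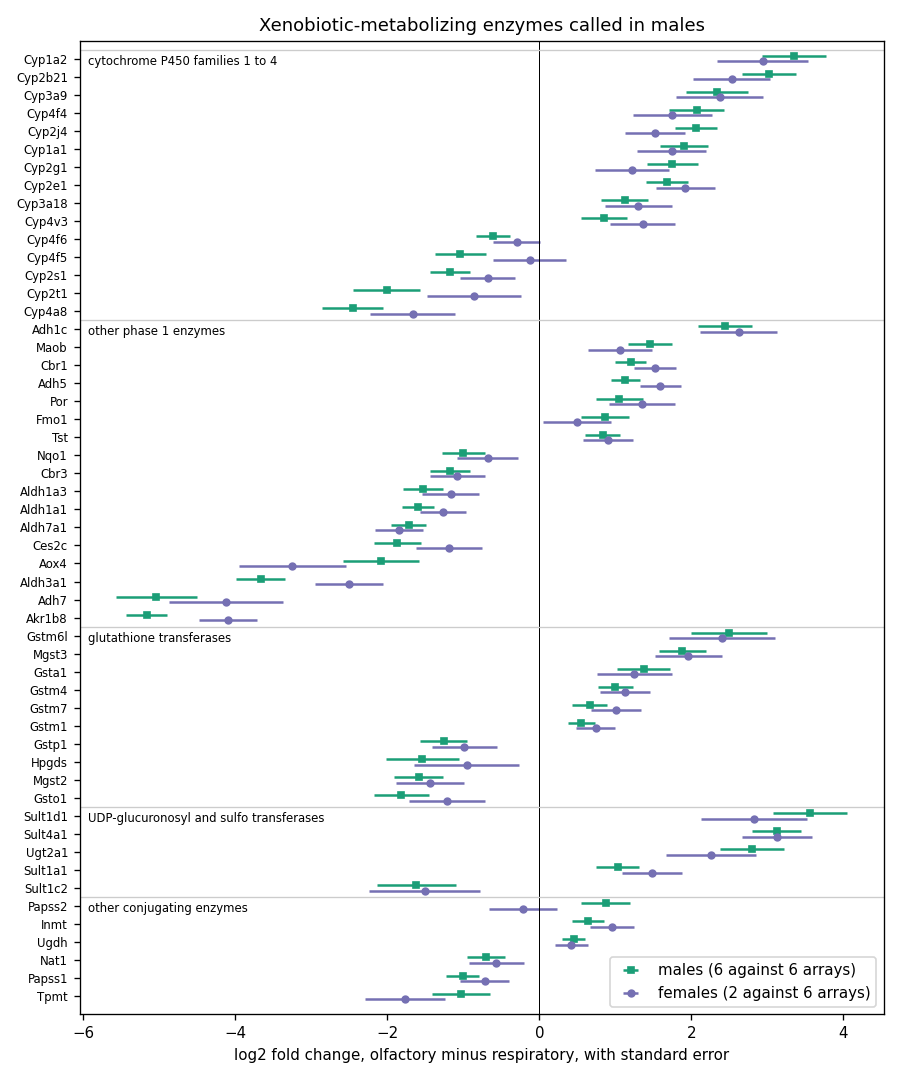
Points give the log2 signal in olfactory minus respiratory epithelium, with SE, of the xenobiotic enzyme genes called in males, for males (6 against 6 arrays) and females (2 against 6 arrays). In males the values run from -5.17 for Akr1b8 to 3.56 for Sult1d1.

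Conjugating enzymes, which attach groups that ease excretion, were also divided. Of 24 glutathione transferase genes 6 rose, with Gstm6l (2.50, SE 0.50) and Mgst3 (1.88, SE 0.31), and 4 fell: Gsto1 (-1.82, SE 0.36), Mgst2 (-1.59, SE 0.32), Hpgds (-1.54) and Gstp1 (-1.26, SE 0.31). UDP-glucuronosyl and sulfo transferases had 4 of 23 genes higher, Sult1d1 (3.56, SE 0.49), Sult4a1 (3.12, SE 0.32), Ugt2a1 and Sult1a1 (1.03, SE 0.28), and 1 lower, Sult1c2 (-1.62, SE 0.52). Among 12 other conjugating enzymes Papss2, Inmt and Ugdh were higher (0.87, 0.64 and 0.45) and Tpmt, Papss1 and Nat1 lower (-1.03, -1.01 and -0.70), while Nnmt was not called (-0.99, adjusted p 0.0935). Of these 6 genes only Papss1 kept its call without each single array: without male respiratory 4 the adjusted p was 0.0974 for Tpmt, 0.0963 for Nat1 and 0.0833 for Inmt, and without male olfactory 7 it was 0.106 for Papss2 and 0.0833 for Ugdh. Hpgds was likewise lost without male respiratory 2 (0.057) and Sult1c2 without male olfactory 1 (0.068). With quantile normalization Tpmt (-0.94, adjusted p 0.077), Nat1 (-0.63, adjusted p 0.112) and Ugdh (0.42, adjusted p 0.0644) were not called. Inmt was not called with the fixed animal block (adjusted p 0.103), and Sult1a1, Inmt and Ugdh were not called within 11 weeks (0.102, 0.281 and 0.155). Neither camera (adjusted p 0.286, 0.268 and 0.979) nor fry (0.336, 0.0674 and 0.146) passed these lists, with 12, 5 and 7 genes passing adjusted over the list alone. The mean of all Papss2 probe sets was not called (0.54, adjusted p 0.269). With the RNA integrity covariate only Gsto1, Mgst2, Gstp1, Sult4a1 and Ugt2a1 of the genes named here stayed called. Calls ended mainly by a larger SE for Gstm6l (2.17, SE 0.88 from 0.50), Hpgds (-1.39, SE 0.97 from 0.49), Sult1c2 (-2.34, SE 1.04 from 0.52), Papss2 (1.06, SE 0.57 from 0.32), Ugdh (0.41, SE 0.28 from 0.15), Tpmt (-1.73, SE 0.73 from 0.38), Papss1 (-0.92, SE 0.42 from 0.22) and Nat1 (-1.13, SE 0.47 from 0.25). By a smaller change as well they ended for Mgst3 (1.16, SE 0.48 from 0.31), Sult1d1 (2.42, SE 0.83 from 0.49), Sult1a1 (0.00, SE 0.44 from 0.28) and Inmt (0.29, SE 0.34 from 0.21).

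Transporters and oxidant defence had more genes lower than higher. Of 23 xenobiotic transporter genes 2 rose, the organic cation carrier gene Slc22a2 (2.95, SE 0.46) and Slco3a1 (0.73, SE 0.23), and 5 fell: Slc22a3 (-3.34, SE 0.37), Slc22a4 (-2.62, SE 0.28), the carnitine carrier gene Slc22a5 (-1.13, SE 0.23), Abcc3 (-0.89) and Abcb4 (-0.86). Of 24 genes listed under oxidant defence 2 rose, the peroxiredoxin genes Prdx2 (0.58) and Prdx6 (0.52), and 8 fell. Among the lower were Gpx2 (-2.59, SE 0.30), Gclc (-1.68, SE 0.26), the catalase gene Cat (-1.27, SE 0.26) and Duox2 (-3.20, SE 0.55). Duox2 is an oxidase that forms hydrogen peroxide, so it is a source of oxidants and not a defence. Of 25 genes listed under xenobiotic and nuclear receptors 4 rose, the retinoic acid receptor gene Rarb (1.68, SE 0.25), Pparg (0.95), Rxrg (0.88) and Thra (0.76). The 5 that fell were the dioxin receptor gene Ahr (-1.50, SE 0.40), its partner Arnt (-1.45, SE 0.41), Rxra (-1.08), Nfia (-0.89) and the glucocorticoid receptor gene Nr3c1 (-0.66). Nfia is a transcription factor and not a receptor. Without single arrays the adjusted p rose to 0.0514 for Slco3a1 (male respiratory 1), 0.0939 for Abcb4 and 0.0524 for Rxrg (male olfactory 4), 0.0563 for Prdx2 (male olfactory 7), 0.0523 for Prdx6 (male respiratory 8) and 0.0706 for Rxra (male respiratory 2). The fixed animal block ended the calls of Arnt (0.121) and Prdx6 (0.0578), and within 11 weeks Arnt (0.288), Abcc3 (0.0714), Abcb4 (0.13), Prdx6 (0.0811), Rxrg (0.203), Rxra (0.203), Pparg (0.0506) and Nfia (0.0513) did not pass. Camera passed none of these lists (adjusted p 0.437, 0.121 and 0.979), while fry called transporters (0.0299) and oxidant defence (0.000398) lower and not the receptors (0.484). In camera the first 2 of these had adjusted p = 0.746 and 0.466 with an estimated correlation, and 8, 11 and 9 genes passed adjusted over the list alone. With quantile normalization Abcb4 was not called (-0.74, adjusted p 0.0698). The mean of all probe sets was not called for Thra (0.38, adjusted p 0.149), Rxrg (0.54, adjusted p 0.0552) and Nr3c1 (-0.51, adjusted p 0.0595). With the RNA integrity covariate only Slc22a2, Slc22a3, Slc22a4, Gpx2 and Rarb of these genes stayed called. Mainly a larger SE ended the calls of Slco3a1 (1.06, SE 0.42 from 0.23), Prdx6 (0.44, SE 0.28 from 0.16), Cat (-1.02, SE 0.41 from 0.26), Thra (0.67, SE 0.33 from 0.20), Arnt (-1.39, SE 0.70 from 0.41), Nfia (-0.81, SE 0.33 from 0.22) and Nr3c1 (-0.53, SE 0.25 from 0.16). A smaller change as well ended the calls of Slc22a5 (-0.68, SE 0.43 from 0.23), Abcc3 (-0.60, SE 0.50 from 0.26), Abcb4 (-0.63, SE 0.55 from 0.29), Prdx2 (0.20, SE 0.27 from 0.18), Duox2 (-1.77, SE 0.99 from 0.55), Gclc (-1.26, SE 0.43 from 0.26), Pparg (0.46, SE 0.41 from 0.23), Rxrg (0.37, SE 0.47 from 0.27), Ahr (-1.02, SE 0.74 from 0.40) and Rxra (-0.34, SE 0.64 from 0.35).

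Basal, goblet and squamous cell genes were lower in male olfactory than in male respiratory epithelium, and motile cilia genes went both ways. Of 15 genes of basal cells, the stem cells of the airway lining, 13 fell, with Krt15 (-4.24, SE 0.22, adjusted p 3.2e-11), Cd44 (-2.80, SE 0.26), Lamb3 (-2.47, SE 0.30), Tp63 (-2.23, SE 0.35) and Krt5 (-1.93, SE 0.35). Goblet and secretory cells had 16 of 26 genes lower, with Muc5ac, the protease inhibitor gene Slpi (-4.66, SE 0.77) and Pigr (-3.94, SE 0.42), which carries antibodies into mucus. Squamous epithelium had 13 of 21 genes lower: Krt6c (-5.13, SE 0.61) and Krtdap (-4.92, SE 0.85) fell, and Lgals7 was at least 21.0-fold lower (adjusted p 1.4e-07). Of 21 genes listed under extracellular proteases and inhibitors of the airway 11 fell, with Elf3 (-2.26, SE 0.23). Elf3 itself is a transcription factor and neither a protease nor an inhibitor. Of 37 motile cilia genes 13 were lower, such as the dynein genes Dnah1 (-2.58, SE 0.26), Dnah2 (-2.39, SE 0.35) and Dnah7 (-2.17, SE 0.28), and 4 higher: Tekt2 (1.22, SE 0.20), Rfx3 (1.11, SE 0.20), Mlf1 (1.11, SE 0.31) and Cfap20 (0.41), the last not without male olfactory 4 (adjusted p 0.124), within 11 weeks (0.0683) or with the fixed animal block (0.0822). Camera passed the basal (adjusted p 2.7e-08), goblet (4.5e-06), squamous (3.3e-06) and protease (0.00121) lists but not cilia (0.117), which passed as lower over all probe sets (0.0393). The basal list kept this with an estimated correlation (adjusted p 0.0492), and goblet, squamous, proteases and cilia did not (adjusted p = 0.085, 0.234, 0.0948 and 0.657 with an estimated correlation). Fry called all 5 lists lower, with adjusted p values up to 0.0131 for cilia. Adjusted over the list alone, 13, 17, 16, 12 and 20 genes passed in the basal, goblet, squamous, protease and cilia lists. The RNA integrity covariate ended calls mainly by a larger SE for Slpi (-4.67, SE 1.48 from 0.77), Tp63 (-1.90, SE 0.58 from 0.35) and Cfap20 (0.50, SE 0.26 from 0.15). By a smaller change as well it did so for Dnah2 (-1.53, SE 0.56 from 0.35) and Mlf1 (0.76, SE 0.57 from 0.31).

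Immune genes were lower in male olfactory epithelium. Of 41 leukocyte genes 29 fell, with the integrin gene Itgax (-3.14, SE 0.50), the pan-leukocyte marker Ptprc (-2.94, SE 0.40) and Cd74 (-2.91, SE 0.29), and 2 rose, both known from mast cells: Cpa3 (1.58, SE 0.38) and Fcer1a (1.34, SE 0.37). All 8 genes of MHC class II, which presents antigen, fell, with RT1-Bb (-3.14, SE 0.85) and RT1-Ba (-2.97, SE 0.43), and 17 of 31 interferon response genes fell, with the immunoproteasome genes Psmb8 (-2.60, SE 0.40) and Psmb9 (-2.26, SE 0.42) and the chemokine gene Cxcl9 (-2.19, SE 0.56). Camera gave adjusted p values of 5.4e-08, 1.2e-05 and 4.5e-06, none kept with an estimated correlation (adjusted p = 0.234, 0.215 and 0.234 with an estimated correlation). Fry called all 3 lists lower (adjusted p 0.000114, 2.7e-05 and 0.000137). Adjusted over the list alone, 34, 8 and 25 genes passed. Fcer1a was not called within 11 weeks (adjusted p 0.103). The RNA integrity covariate ended calls mainly by a larger SE for Itgax (-3.15, SE 0.95 from 0.50), Cpa3 (1.27, SE 0.70 from 0.38) and Cxcl9 (-2.81, SE 1.09 from 0.56). By a smaller change as well it did so for Fcer1a (0.56, SE 0.66 from 0.37) and RT1-Bb (-1.69, SE 1.62 from 0.85).

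Of 23 endothelial genes 14 fell, with Ramp2 (-2.52, SE 0.24), Pecam1 (-2.28, SE 0.40) and Plvap (-2.05, SE 0.35), and 1 rose, the tight junction gene Cldn5 (2.03, SE 0.31). Of 34 genes of connective tissue, bone and cartilage 15 fell, with Acp5 (-2.40, SE 0.28), the osteoclast phosphatase, and Alpl (-1.78, SE 0.29), and the cartilage collagen gene Col9a1 rose, at least 1.42-fold (adjusted p 0.000168). Erythrocytes had 4 of 8 genes lower, Alas2 (-2.24, SE 0.45), Hba-a3, Epb42 (at least 1.07-fold, adjusted p 0.00231) and Hbb (-0.67), and 1 higher, Tmcc2 (1.96, SE 0.44), with Hbb lost without male olfactory 2 (adjusted p 0.0777). Of 24 skeletal muscle genes Tnni2, Pvalb and Neb fell (-1.71, -1.40 and -1.30) and Myl11 rose (2.34, SE 0.83), though not without male respiratory 4 (adjusted p 0.114), and Tnnc2 was not called (1.65, adjusted p 0.153). By camera the endothelial (adjusted p 3.6e-05) and connective (0.00305) lists passed, and neither did with an estimated correlation (adjusted p = 0.0855 and 0.396 with an estimated correlation), while erythrocytes (0.226) and muscle (0.979) did not pass. Fry gave adjusted p values of 1.1e-06, 0.000685, 0.0674 and 0.568 for these 4 lists. The muscle list's median (0.07) and mean (-0.03) differ in sign. Adjusted over the list alone, 17, 18, 5 and 3 genes passed. Within 11 weeks Epb42 (adjusted p 0.0794), Tmcc2 (0.0803), Neb (0.23) and Myl11 (0.27) were not called. The mean of all Neb probe sets was not called either (-0.19, adjusted p 0.603). Under the RNA integrity covariate calls ended mainly by a larger SE for Alpl (-1.68, SE 0.55 from 0.29), Hba-a3 (adjusted p 0.0837, SE 0.91 from 0.49), Epb42 (adjusted p 0.17, SE 0.56 from 0.32), Hbb (-1.05, SE 0.41 from 0.23) and Pvalb (-1.66, SE 0.56 from 0.31). They ended by a smaller change as well for Cldn5 (1.40, SE 0.43 from 0.31), Tmcc2 (1.00, SE 0.78 from 0.44), Neb (-0.65, SE 0.66 from 0.35) and Myl11 (0.77, SE 1.30 from 0.83).

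Among lists of cell state, 10 of 33 cell cycle genes fell in males, with the mitotic kinase gene Aurkb (-2.52, SE 0.47), Kif23 (-1.70, SE 0.24) and Bub1b (-1.42, SE 0.46), the last not without male olfactory 10 (adjusted p 0.0619) or within 11 weeks (0.302). Of 27 immediate early and heat shock genes 9 fell, with Klf4 (-2.30, SE 0.23) and Myc (-1.91, SE 0.26), regulators of transcription. Circadian clock genes were split, Bhlhe40 (-2.10, SE 0.36) and Clock (adjusted p 0.00279) lower and Bhlhe41 (0.92, SE 0.26) and Cry1 (0.77, SE 0.24) higher among 18, with Per3 not called (-1.39, adjusted p 0.134). Clock did not pass with the fixed animal block (adjusted p 0.0684), Cry1 not without male respiratory 4 (0.0662), and Bhlhe41 and Cry1 not within 11 weeks (0.0801 and 0.0545). Of 23 genes of androgen and oestrogen response 11 fell, with Klk8 (-1.78, SE 0.43) and Areg (at least 1.33-fold, adjusted p 0.00792), and 1 rose, the steroid-induced gene Fkbp5 (1.11, SE 0.18), while Esr2 was at background in both male groups. Sex-dimorphic genes of rat liver had 9 of 33 lower and 2 higher, Cyp3a18, at background on all male respiratory arrays (adjusted p 0.00986), and Fmo1 (0.86, SE 0.32). Fmo1 was lost without male respiratory 2 (adjusted p 0.129) and with quantile normalization (0.0667), and Cyp3a18 with the fixed animal block (0.0559) and within 11 weeks (0.0509). In limma 0 of 4 Y-linked genes passed, 0 of them at an unadjusted p under 0.05, and 0 of 8 X genes that escape or drive inactivation, 1 of them at an unadjusted p under 0.05. Camera passed the cell cycle (adjusted p 0.00305), immediate early (0.0031) and hormone response (0.0244) lists, and none did with an estimated correlation (adjusted p = 0.538, 0.396 and 0.085 with an estimated correlation). The cell cycle list also did not pass with the RNA integrity covariate (0.0992), and the hormone response list neither without male respiratory 7 (0.0506) nor within 11 weeks (0.153). Clock (0.979), liver (0.204), Y-linked (0.979) and X (0.979) lists did not pass, and the clock list's median (0.07) and mean (-0.11) differ in sign. The liver list did pass as lower over all probe sets (0.000482) and by fry (1.1e-06), but had adjusted p = 0.238 with an estimated correlation. Fry also called the cell cycle (0.00822), immediate early (0.00132) and hormone response (1.2e-08) lists lower, and not the clock (0.702), Y-linked (0.622) and X (0.812) lists. Adjusted over the list alone, 11 cell cycle, 9 immediate early, 4 clock, 12 hormone response and 11 liver genes passed, and no Y-linked or X gene did. Under the RNA integrity covariate calls ended mainly by a larger SE for Clock (adjusted p 0.0775, SE 0.34 from 0.24), Bhlhe41 (0.93, SE 0.53 from 0.26), Cry1 (1.18, SE 0.38 from 0.24), Klk8 (-1.85, SE 0.79 from 0.43) and Areg (adjusted p 0.0677, SE 0.87 from 0.46). They ended by a smaller change as well for Aurkb (-1.27, SE 0.84 from 0.47), Bub1b (-0.99, SE 0.86 from 0.46), Bhlhe40 (-1.58, SE 0.58 from 0.36), Cyp3a18 (adjusted p 0.402, SE 0.49 from 0.31) and Fmo1 (0.67, SE 0.64 from 0.32).

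In females the same question rested on 2 olfactory against 6 respiratory arrays, and the picture was alike for the strongest genes. The 20 genes with the largest changes in males all moved the same way in females, and 19 of them passed, the exception being Dnase1 (-2.90, SE 1.07, adjusted p 0.0622). Tmem213 (4.81, SE 0.77), Faim2 (4.46, SE 0.71), Rgr (4.24, SE 0.70), Gpr162 (3.93, SE 0.60) and Nrn1l (3.90, SE 0.52) were higher. Inhca (-6.31, SE 0.62), Csn3 (-5.53, SE 0.64), Muc5ac (-4.60, SE 0.63) and Mup5 (-4.55, SE 0.83) were lower, and Kcne1, at background on both olfactory arrays, was at least 84.7-fold lower (adjusted p 4.1e-07). Omp (3.03, SE 0.60), Cnga2 (2.93, SE 0.57), Adcy3 (3.52, SE 0.48), Stmn3 (3.84, SE 0.57), Uchl1 (3.25, SE 0.48) and Sult4a1 (3.12, SE 0.46) rose, as did Cyp1a2 (2.94, SE 0.60), Cyp2b21 (2.53, SE 0.51) and Adh1c (2.62, SE 0.51). Akr1b8 (-4.10, SE 0.38), Adh7 (-4.13, SE 0.75), Aldh3a1 (-2.51, SE 0.45), Krt15 (-3.28, SE 0.32), Cd44 (-3.24, SE 0.36), Ptprc (-3.24, SE 0.57) and Cd74 (-2.51, SE 0.42) fell. Obp1f did not pass (-0.75, SE 0.88, adjusted p 0.613). The median change of all probe sets was -0.11 with the deposited scaling and 0.02 with quantile normalization. In limma 5571 probe sets passed, 2371 higher and 3200 lower, and 4810 of them changed 2-fold or more (1901 higher, 2909 lower), including 3201 named genes. Of these probe sets 1925 were higher in both sexes, where independent calls would give 274.5, and 2211 were lower in both, where they would give 436.1, while 2 higher in males were lower in females. The count fell to 1977 without female olfactory 6 and to 2992 without female olfactory 8, and was 1133 with the RNA integrity covariate, which kept 41 of the 127 named genes called here. On the same arrays without it 6235 passed. Of the 19 genes above 10 were called with that covariate. Of the genes named in this paragraph it ended the calls of Adh7 (-4.08, SE 1.17 from 0.75) and Ptprc (-2.80, SE 0.78 from 0.57) mainly by a larger SE. It ended those of Tmem213 (2.99, SE 0.94 from 0.77), Rgr (3.10, SE 1.04 from 0.70), Omp (2.37, SE 0.69 from 0.60), Cyp1a2 (1.76, SE 0.55 from 0.60), Cyp2b21 (1.5, SE 0.57 from 0.51) and Adh1c (1.40, SE 0.54 from 0.51) at less than 0.8 times the former change.

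Among the gene lists in females, higher genes made up 12 of 17 in olfactory transduction (median 2.53), 12 of 18 receptors, 16 of 21 in immature neurons and 12 of 23 in synapse and excitability, and lower genes 9 of 15 in basal cells (median -1.45), 8 of 26 in goblet cells, 9 of 21 in squamous epithelium, 18 of 41 leukocyte genes (median -1.49), 5 of 8 in MHC class II, 10 of 31 in interferon response, 9 of 23 in endothelium, 10 of 34 in connective tissue and 6 of 33 in cell cycle. These 13 lists passed by camera, with adjusted p values from 1.4e-10 for immature neurons to 0.0187 for cell cycle, and none of them with an estimated correlation, where the smallest was adjusted p = 0.162 with an estimated correlation. Cell cycle did not pass without female respiratory 8 (adjusted p 0.12) or 9 (0.0998), with quantile normalization (0.0764) or with the RNA integrity covariate (0.131). Over all probe sets it did not pass either (0.068), while sustentacular cells (0.0101) and UDP-glucuronosyl and sulfo transferases (0.0133) passed as higher (adjusted p = 0.572 and 0.504 with an estimated correlation). Fry called 12 of the 13 lists in the same direction, all but cell cycle (adjusted p 0.0841). It also called UDP-glucuronosyl and sulfo transferases higher (0.0332) and the X (0.0332), liver (0.00672), hormone response (1.8e-05) and protease (0.0443) lists lower, whose camera values with an estimated correlation were 0.504 for the first, 0.175 for hormone response and 0.572 for each of the others. Adjusted over the list alone, 13 transduction, 12 receptor, 18 immature neuron, 12 synapse, 11 basal, 10 goblet, 11 squamous, 27 leukocyte, 6 MHC class II, 14 interferon, 11 endothelial, 11 connective tissue and 6 cell cycle genes passed. The cytochromes P450 had 9 genes higher and 3 lower (camera adjusted p 0.286), other phase 1 enzymes 4 and 8 (0.597), glutathione transferases 5 and 1 (0.235), and UDP-glucuronosyl and sulfo transferases 6 higher (0.0647).

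The markers of smell were also present in respiratory samples, to an unequal degree. On the 6 male respiratory arrays the mean of the olfactory transduction list was 7.98 ± 0.43 (SD) with 1 array at 8.83, and on the 6 female respiratory arrays 8.62 ± 0.67, from 7.91 to 9.66, against 10.42 ± 0.25 (n = 6) and 10.45 ± 0.08 (n = 2) in olfactory arrays. Without the 3 respiratory arrays highest in Omp, a comparison chosen after seeing the data, 6979 probe sets passed in males and 4502 in females.

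A further comparison asked whether the sexes differ within each tissue. In respiratory epithelium (6 female against 6 male arrays) the genes of the sex chromosomes parted the groups and few others did. Xist, the RNA that silences 1 X chromosome in females, was higher in females on all 4 of its probe sets: by 4.92 (SE 0.31, adjusted p 7.2e-10) on 1377971_at, at least 60.2-fold (adjusted p 3.8e-14) on 1374684_at, at least 20.1-fold on 1386785_a_at and at least 14.7-fold on 1386786_at. Eif2s3y, a translation factor gene of the Y chromosome, was at least 47.5-fold lower in females (1393237_at, adjusted p 7.1e-15). The other 3 calls were probe sets with no gene named here, 1375535_at (5.46, SE 0.27) and 1379834_at (3.00, SE 0.35) higher and 1369317_at lower (-2.74, SE 0.49, adjusted p 0.0487, 0.181 without male respiratory 8, 0.0834 with quantile normalization, and 0.25 with the RNA integrity covariate, at -3.11 and SE 0.60). In all 8 probe sets passed, 6 higher and 2 lower in females, and 1160 had an unadjusted p under 0.05. Within rats aged 13 weeks (3 female arrays against 1 male array, which is assumed to vary like the females) 7 passed. Within 14 weeks (2 against 2 arrays, among them female respiratory 8 and male respiratory 7, which stand apart) 4 passed. There Xist was not called on 1377971_at (4.67, SE 0.74 from 0.31, adjusted p 0.16) or on 1386786_at (SE 0.81 from 0.32, adjusted p 0.248), nor was 1379834_at (3.29, SE 0.69 from 0.35, adjusted p 0.993, and 0.871 within 13 weeks), each with a larger SE on fewer arrays. The probe set 1369317_at was called within neither age (adjusted p 0.871 and 1). The X copy Eif2s3 (0.62, SE 0.15, adjusted p 0.534) and Kdm5c (0.54, SE 0.18, adjusted p 1) were not called, nor was the probe set named Uty (0.78, SE 0.18, adjusted p 0.387). Tspy1 was at background in every group and Sry near it. Of the liver genes with a sex difference Lifr (0.85, SE 0.31), Cux2 (-0.79, SE 0.34) and Hsd3b5 (0.66, SE 0.38) had an adjusted p of 1. In simulated arrays of the same number 90.9% of genes changed by log2 2 and 22.4% of those changed by log2 1 were recovered.

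**Figure D4:**
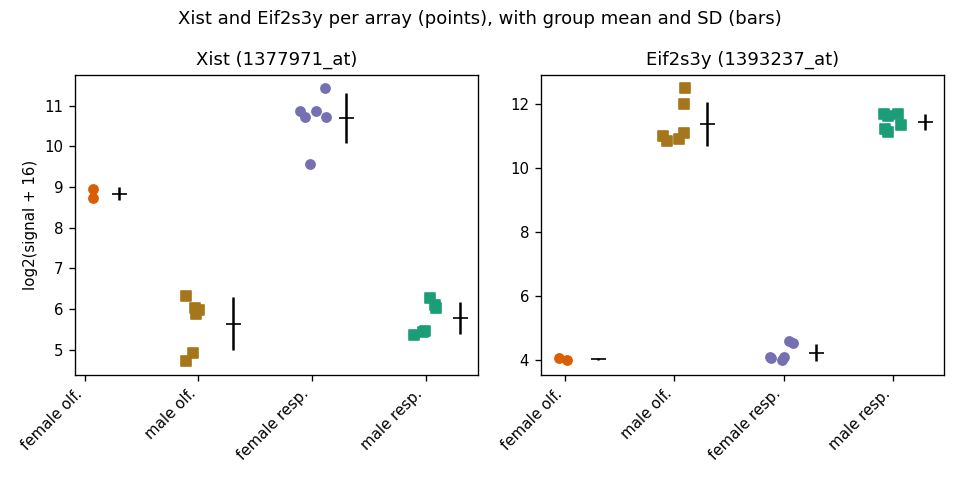
Log2 signal of Xist (1377971_at) and Eif2s3y (1393237_at) on each of 20 arrays by sex and tissue, with the group mean and SD. Xist averages 10.69 in female respiratory and 8.83 in female olfactory arrays against 5.78 and 5.64 in males, and Eif2s3y 4.24 and 4.04 in females against 11.45 and 11.39 in males.

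Between the sexes in respiratory epithelium 9 lists passed by camera and 1 of them with an estimated correlation. The X list was higher in females (adjusted p 1.8e-12, and 0.00183 with an estimated correlation), with 1 of 8 genes called and 3 adjusted over the list alone. The Y-linked list had 1 of 4 genes lower and 2 called adjusted over the list alone (adjusted p 0.0516). Olfactory transduction was higher in females with a median of 0.73 but 0 of 17 genes called in limma and 8 at an unadjusted p under 0.05 (camera adjusted p 1.2e-09, adjusted p = 0.172 with an estimated correlation, and 0.065 within 14 weeks). Camera also passed olfactory receptors (adjusted p 0.0122), synapse (0.037) and squamous epithelium (0.00342) as higher, and MHC class II (0.00012, median -0.59), connective tissue (0.00332), cell cycle (0.00012) and immediate early genes (0.00012) as lower. None of these 7 passed with an estimated correlation, where the smallest was adjusted p = 0.466 with an estimated correlation. Fry called the X (adjusted p 2.4e-05) and Y-linked (9.9e-08, and adjusted p = 0.293 with an estimated correlation in camera) lists and none of the other 8 that passed camera. Over all probe sets receptors, synapse and squamous epithelium did not pass (0.0753 each) and proteases did, as lower (0.0138, and adjusted p = 0.607 with an estimated correlation). Leaving out 1 array ended the calls of receptors (0.101 without female respiratory 8), synapse (0.57 without female respiratory 7), squamous epithelium (0.335 without female respiratory 3), connective tissue (0.0845 without female respiratory 9) and immediate early genes (0.051 without male respiratory 2). Without female respiratory 9 the number of lists passing rose from 9 to 17, without female respiratory 8 to 14, and without female respiratory 3 it fell to 6. Within 14 weeks, with 2 against 2 arrays of which female respiratory 8 and male respiratory 7 stand apart, receptors (0.287), synapse (0.802), MHC class II (0.553) and immediate early genes (0.802) did not pass and squamous epithelium and cell cycle passed in the opposite direction (0.00339 and 0.0434). Within 13 weeks, with 3 against 1 array, receptors (0.0781), squamous epithelium (0.741) and connective tissue (0.427) did not pass.

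In olfactory epithelium (2 female against 6 male arrays) the same sex chromosome genes led. The female arrays came from rats of 13 and 14 weeks, the male ones from rats of 11 to 14 weeks. On the second principal component the olfactory arrays of 11 weeks, all male, lay at 40.58 to 84.41 and the other olfactory arrays at -68.09 to 4.04. Age and sex are thus partly confounded in this contrast. Eif2s3y was at least 41.6-fold lower in females (adjusted p 9.1e-12), and Xist was higher by 3.19 (SE 0.44) on 1377971_at, by 2.77 (SE 0.45) on 1386786_at, at least 21.5-fold on 1374684_at (adjusted p 2.3e-08) and at least 5.98-fold on 1386785_a_at. The unnamed 1375535_at was higher by 4.21 (SE 0.38) and 1379834_at at least 6.39-fold. Thoc3 and Lrfn2 were at least 1.27-fold and 1.28-fold higher (adjusted p 0.00549 and 0.0226), and Mical2, Optn and the interferon receptor gene Ifnar1 at least 1.68-fold, 2.02-fold and 2.70-fold lower (adjusted p 0.00214, 0.0231 and 0.0456), with unnamed 1379347_at lower by -2.01 (SE 0.35, adjusted p 0.0226). In all 13 probe sets passed, 8 higher and 5 lower, 1583 had an unadjusted p under 0.05, and the count was 8 without female olfactory 6 and 26 without male olfactory 4. Without female olfactory 6 the adjusted p was 0.0864 for Mical2, 0.341 for Lrfn2, 0.455 for Optn and 0.297 for 1379347_at. Without female olfactory 8 it was 0.0878 for Xist on 1377971_at, 0.257 for Xist on 1386786_at, 0.173 for 1379834_at, 0.152 for Thoc3 and 0.477 for Ifnar1. The mean of all probe sets was not called for Thoc3 (adjusted p 0.534), Optn (0.539), Mical2 (0.909) and Ifnar1 (0.981). With the RNA integrity covariate Optn (adjusted p 0.105, SE 0.35 from 0.34) and Ifnar1 (0.0903, SE 0.42 from 0.45) were not called, at 0.91 and 0.898 times the former change. Camera passed 7 lists, 4 as higher and 3 as lower in females, of which the Y-linked list (lower, adjusted p 0.00305) also passed with an estimated correlation (adjusted p 0.0378). Of its 4 genes 3 lay at background on all arrays of a group. At an unadjusted p under 0.05 in limma 1 was lower, Eif2s3y, and 1 higher, so the call rests on Eif2s3y. With array quality weights, chosen after seeing the data, no list passed (0.0542 for the Y-linked list). With quantile normalization the X (0.0772) and cell cycle (0.211) lists did not pass. The number of lists fell to 3 without female olfactory 6 and to 4 without female olfactory 8, male olfactory 4 or male olfactory 10. The X list (0.022), proteases (0.0153), squamous epithelium (0.00305), connective tissue (0.0116), cell cycle (0.0256) and motile cilia (0.0129) passed camera but not with an estimated correlation, where the smallest was adjusted p = 0.606. Each was lost without 1 array: the X list (0.212) and cilia (0.216) without female olfactory 6, proteases (0.279), cell cycle (0.204) and squamous epithelium (0.964) without female olfactory 8, and connective tissue (0.132) without male olfactory 4. Fry called only the Y-linked list (9.1e-07). Over all probe sets connective tissue (0.0703), cell cycle (0.264) and proteases (0.26) did not pass, and UDP-glucuronosyl and sulfo transferases and the liver list passed as higher (0.0316 each, and adjusted p = 0.889 each with an estimated correlation).

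Whether the tissue difference itself depended on sex was tested as an interaction. No gene passed: 0 of 31042 probe sets in limma, with 1516 at an unadjusted p under 0.05, and 2 without female olfactory 6 and 1 without female respiratory 7 or male respiratory 7. Xist was lower in female olfactory than in female respiratory epithelium, by -1.86 (SE 0.44, adjusted p 0.00508) on 1377971_at, which was lost without female olfactory 6 (adjusted p 0.0884). With the RNA integrity covariate it was not called (-1.49, SE 0.65, adjusted p 0.231), nor were its other 3 probe sets (adjusted p 0.103, 0.166 and 0.335). In males it stayed near background, and its interaction did not pass (-1.72, SE 0.54, adjusted p 0.924). In simulated arrays 43.9% of interactions of log2 2 and 1.5% of those of log2 1 were recovered. Camera passed 3 lists, olfactory transduction (adjusted p 0.0104, median -0.63), X genes (0.0418) and proteases (0.00956), none of them with an estimated correlation (adjusted p = 0.934, 0.89 and 0.731 with an estimated correlation), and none without female olfactory 8 (0.127, 0.356 and 0.145) or by fry (0.971, 0.859 and 0.579). Over all probe sets these 3 passed and 4 further lists did, UDP-glucuronosyl and sulfo transferases, motile cilia and squamous epithelium (0.0286 each) and liver genes (0.0153), with adjusted p = 0.934 each with an estimated correlation. The number of lists was 5 without male respiratory 1 and 1 without female respiratory 7.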

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

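The tests of carried-over olfactory tissue, of a sex difference, of plain dilution, of degraded RNA and of gland tissue were chosen only after the results they measure were seen.

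On the 12 respiratory arrays the olfactory signal transduction list varied widely, and male respiratory 1 stood apart from the other 5 male arrays at a mean of 8.827. Olfactory tissue collected along with respiratory tissue is a candidate explanation: the list of sustentacular cells, which are not neurons, followed it with Pearson's r 0.839 (95% interval 0.512 to 0.954, permutation p 0.00056, adjusted 0.00224 over 4 correlations) and Spearman's rho 0.867 (permutation p 0.00053), and r stayed at 0.788 without female respiratory 7 and 3, at 0.928 within the females and at 0.805 within the males. RNA quality cannot be told apart as a further contributor, since the GAPDH 3' to 5' ratio gave r 0.324 (permutation p 0.291, rho 0.545, permutation p 0.0697) with an interval from -0.307 to 0.757 that 12 arrays leave wide. The correlation with the RNA integrity number was not tested. Female respiratory 7, 6 and 8 had the lowest numbers (8.7, 8.9 and 8.7) and list means of 9.66, 8.68 and 8.41. Female respiratory 3 reached 9.07 at a number of 9.2. The other arrays with a number (9.1 to 9.3) lay from 7.61 to 7.98. A sex difference, which the design names, also stays open: the list mean was higher by 0.64 in females with an exact permutation p of 0.0844 over 924 splits. Tissue was collected by hand, and no record of the dissection was used here.

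Lists of leukocytes, MHC class II, basal cells and stroma were lower in male olfactory epithelium. Plain dilution by more olfactory cells would lower all lists alike if those cells expressed none of the members, which was not tested. Among well-measured members (mean log2 above 8) MHC class II changed by -2.48, basal cells by -2.10 and leukocytes by -1.73. Connective tissue changed by -0.83, endothelium by -0.80 and motile cilia by -0.37. MHC class II and connective tissue differed by -1.649 (exact permutation p 0.00433 over 924 splits). This argues against dilution by cells that lack all these genes as the whole cause. Dilution by cells that express some of them stays open. Unevenness between arrays left after the deposited scaling is argued against by the array medians. They differed by -0.10 log2 between the male tissues, far less than the leukocyte median (-1.57). Quantile normalization could therefore move that median little, and it left it at -1.504. Whether the deposited scaling itself shifted these lists cannot be decided, since it had already set the arrays to a common level. A true difference between the tissues, which the design names, stays open and may be joined by unequal collection, which was not tested for these lists.

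Female respiratory 8 and male respiratory 7 stood apart from the other arrays of their groups, at -113.35 and -97.55 on the second and 96.76 and -74.35 on the third principal component. Their 100 brightest probe sets held 17.209 and 13.984% of all signal, and female respiratory 8 also had the lowest median of its group (log2 7.317) and the highest Obp1f (log2 15.776). Degraded RNA cannot be told apart in female respiratory 8: its 3' to 5' ratios exceeded the highest of the other 10 respiratory arrays by 0.284 (GAPDH) and 0.405 (beta-actin), but by -0.837 for hexokinase, where its ratio of 0.539 lay under the lowest of them (0.838). In male respiratory 7 all 3 excesses were negative (lowest -0.465), so its ratios do not set it apart from the other 10 arrays. Its GAPDH ratio (0.4006) was still the highest of the male respiratory arrays, and its labels give no RNA integrity number, so degraded RNA is not excluded there. Scaling is argued against by a gap of 94.2 to the other 10 arrays that remained after quantile normalization (92.1 as deposited). More gland tissue in both collections cannot be told apart: both exceeded the other 10 arrays in the gland list mean, the nearer one by 0.151 and by 0.108 without Obp1f, but this held for 5 of 18 members and also for 4 other lists, erythrocytes (0.265), glutathione transferases (0.175), hormone response (0.046) and leukocytes (0.016). Without both arrays 9911 probe sets passed in males and 8484 in females, a comparison chosen after seeing the data.

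Muc5ac on male olfactory 2 lay far below the other male olfactory arrays, at log2 4.706, but under the background of that array (5.665), so its distance from the others (6.423 to 7.202) is not that of a measured level. In all 105 groups of values were screened and 10 had an array far from the others, where chance gives about 1 in 20.

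The tissue difference in females minus that in males passed camera for olfactory signal transduction (adjusted p 0.0104), for X genes (0.0418) and for extracellular proteases and inhibitors (0.00956). None had a call by fry (adjusted p 0.971, 0.859 and 0.579) or with an estimated correlation in camera (0.934, 0.89 and 0.731). Without female olfactory 8 none passed (0.127, 0.356 and 0.145). Without female respiratory 7 camera passed 1 list, as higher, so olfactory transduction, which was lower here, was lost with that array too. The transduction list averaged 10.42 in male and 10.45 in female olfactory arrays, but 7.98 in male and 8.62 in female respiratory arrays. By these means the sexes differed mainly in the respiratory arrays, where female respiratory 7 was highest (9.66).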

How the results depend on the processing

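Leaving out the 2 arrays that stand apart, leaving out the 3 respiratory arrays highest in Omp, array quality weights and only the arrays with an RNA integrity number were chosen after seeing the data. The number of probe sets passing in males stayed within 1.5 times 7824 under every alternative run (gene means gave 4622 genes against 4517) except the RNA integrity covariate, which gave 2347 (2247 of them shared) and in females 1133 (1078 shared). On the same arrays without the covariate 7203 and 6235 passed. In males the 3 arrays fewer thus give a small part of the fall and the covariate the rest. In females only the covariate lowers the count. The RNA integrity numbers do not overlap between the tissues, at 8.2 to 8.8 against 9.1 to 9.3 in males and 8.3 against 8.7 to 9.3 in females. Whether the covariate takes out tissue difference or an effect of RNA quality can therefore hardly be told apart by this design. A call that it ended may still be a tissue difference. In females the count also moved to 8484 without the 2 arrays that stand apart and 8526 with array weights. Animals as a random replicate block gave 8034 in males and 5663 in females and as a fixed block 7493 in males. The random block ended no named call in males and 1 in females, and the fixed block ended 10 of 165. Between sexes in respiratory epithelium the 8 became 3 above the median signal, where fewer probe sets were tested, 4 within 14 weeks, where fewer arrays were, and 18 with array weights. In olfactory epithelium the 13 became 29 with pseudocount 1, 22 with quantile normalization, 6 above the median signal, 23 with no variance trend, 5 with only the groups compared, 26 without the 2 arrays that stand apart and 27 with only the arrays with an RNA integrity number, and gene means gave 5 genes against 3. The interaction count of 0 became 4 with pseudocount 1, 1 with pseudocount 64, 1 with quantile normalization, 2 with no variance trend and 4 with array weights. Except where fewer units or arrays are named, the cause was not tested. Leaving out single arrays gave 6807 (without male respiratory 4) to 8821 (without female respiratory 8) in males, 1977 (without female olfactory 6) to 7361 (without female respiratory 8) in females, 7 to 9 and 8 (without female olfactory 6) to 26 (without male olfactory 4) between sexes in respiratory and olfactory epithelium, and 0 to 2 interactions (2 without female olfactory 6). The 16 lists called in males ranged from 15 to 17 over these, were 19 with all probe sets, and fell to 3 with an estimated correlation, which by its construction widens the spread of a list of genes that move together. Of the named genes called in males 82 of 165 and in females 37 of 127 passed in the same direction under every alternative run, and the RNA integrity covariate kept 83 and 41. It turned Sult1a1 in males to -0.004 (adjusted p 0.998), and the mean of all probe sets turned Thra in females to -0.293 (adjusted p 0.474). For the sex difference in respiratory epithelium lists turned within single ages, with camera adjusted p 0.000897 for erythrocytes within 13 weeks (3 female arrays against 1 male array, assumed to vary like the females) and, within 14 weeks (2 against 2, among them the 2 arrays that stand apart), 0.00111 for other phase 1 enzymes, 0.00339 for squamous epithelium, 0.00501 for leukocytes, 2.58e-06 for interferon response, 0.0434 for cell cycle and 0.802 for immediate early genes. In olfactory epithelium squamous epithelium turned without female olfactory 8 (0.964) and had 1.42e-09 without female olfactory 6. The cause of these turns was not tested. Signal over background limits dim genes: where a group lay at background on all arrays, such as Kcne1 in female olfactory epithelium, only a bound can be given.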

Other observations

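The test of the Uty probe set and the ionocyte and tuft cell lists were chosen only after the values were seen, the mast cell list after Cpa3 and Fcer1a had been seen, and the tests by other splits of the arrays before.

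Of 14 measured mast cell genes 4 were higher in male olfactory epithelium, the mast cell protease genes Mcpt1 (2.84, SE 0.55), Mcpt9 (2.28, SE 0.45), Mcpt10 (2.83, SE 0.48) and Tpsb2 (0.94, SE 0.26), and 3 were lower, the stem cell factor receptor gene Kit (-1.50), Enpp3 (-4.10) and Rab27b (-0.55), which other cells also express. The median was 0.32, 8 passed adjusted over the list alone, and in females 3 were higher and 3 lower. More mast cells in the olfactory collections may lie behind the rise of Cpa3 and Fcer1a. With 4 of the 14 higher, under the 7 that would have been needed, and more higher than lower, this cannot be told apart from a change in a few protease genes, as a list whose members go both ways does not decide it.

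Rare epithelial cells gave mixed results. Of 12 ionocyte genes, from the chloride and acid handling cells of the airway, Atp6v0a4 (1.73) and Coch (0.61) were higher and Tfcp2l1 (-2.48) and Atp6v1c2 (-0.69) lower in male olfactory epithelium (median -0.03, 4 adjusted over the list alone, and 1 higher and 3 lower in females). Of 11 genes of tuft and chemosensory cells Pou2f3 (2.07), the regulator of their identity, and Dclk1 (0.87) were higher and Ptgs1 (-2.54), Alox5ap (-0.98) and Gnat3 (-0.90) lower (median -0.48, 5 adjusted over the list alone, and 1 higher and 1 lower in females).

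The probe set named for the Y-linked gene Uty may measure its X-linked copy. Its signal lay above background on 8 of 8 female arrays and on 12 of 12 male arrays, whereas that of Eif2s3y did so on 0 of 8 female and 12 of 12 male arrays.

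Other splits of the arrays show how far chance can be excluded. Of 100 splits of the 12 male arrays drawn from 462, the real one included, 1 gave as many probe sets as the 7824 of the tissue split, and the highest other gave 5306 with 1 array on each side moved. Of the 32 splits that part both arrays of all 5 animals, 1 gave as many, and the highest other gave 2315, so chance can be excluded for this count. For the count of 16 gene lists it cannot, since 14 of 100 splits gave as many, up to 21, with a median of 9 in the others. Splits that mix the tissues unevenly still carry part of the tissue difference, and the count does not tell which lists pass or how strongly. It thus decides nothing about single lists. Between females and males in respiratory epithelium 2 of 100 splits gave as many as 8 probe sets, with 10 in the highest other, so chance can be excluded at 0.05. As many as 9 lists came from 56 of 100 splits, up to 18 and with a median of 9 in the others. For the number of lists chance can therefore not be excluded.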
